A study of Bos indicus x Bos taurus with 11 samples.

How the data were processed

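Total RNA was sequenced from primary skin fibroblast cultures of 11 bovine fetuses at day 105 of gestation, 1 library per fetus. The fetuses were F1 hybrids of Brahman (Bos taurus indicus) and Angus (Bos taurus taurus) cattle, so that reads over sites where the breeds differ can be assigned to a parent. Per the labels' protocols, the 5 control fetuses (CON_B) came from artificial insemination. The 6 fetuses with large offspring syndrome (LOS) came from assisted reproduction, and their body weight exceeded the 97th centile of the controls. Libraries were depleted of ribosomal RNA and sequenced as 150 bp paired ends with 33 M read pairs planned per sample, per the labels' protocols.

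The submitters' processing notes name FastQC 0.11.7, HISAT2 2.1.0, SAMtools 1.8, StringTie 2.1.4, Cufflinks 2.2.1, Salmon 0.11.1, GATK, Picard 2.22.4 and edgeR 3.36.0, with genome build ARS-UCD1.2. The role of each tool, the counting rule, the use of strand and the rule for calling heterozygous sites are not given in the sources used here. A first table deposited by the authors holds expected counts (estimated reads) per gene for 21862 annotated genes and 5536 loci assembled by the authors. Its values are not normalised, and 71.2% of them are whole numbers with no tolerance allowed. A second table holds whole read counts assigned to the maternal or the paternal allele of 9716 genes, per the file headers. In that table a gene has reads in a library almost only where both alleles were seen: of 79210 gene and library pairs with reads, 6 had 1 allele at 0. A gene expressed strictly from 1 allele would therefore be missing from it, and so would a gene without a heterozygous site. The third table deposited by the authors holds, for 4347 genes, the expected counts multiplied by the allelic share. This product was checked for every gene and library, and 0 values lay beyond a tolerance of 0.001. How reads shared between a gene and its pseudogenes were counted is not given in the sources used here, so values of multicopy genes such as ribosomal protein genes and HMGB1 are uncertain.

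Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16: trimmed mean of M values (TMM) factors, filterByExpr with the design, and quasi-likelihood tests with sex and group as terms. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are LOS minus control or male minus female, given with their standard errors, and CPM are counts scaled to the TMM library sizes. The effect of LOS was also fitted in each sex with a group by sex interaction, which is the test of a difference between the sexes. For the allelic share, the edgeR model had a term for each library, the allele, and allele by group. It covered genes with a mean of 20 or more allelic reads per library, and with 10 or more reads in at least 3 libraries of each group. The expression of each parental allele was tested from the third table with the TMM factors of the total counts. X-linked and mitochondrial genes were left out of the edgeR tests of the allelic share and of each allele. They were not removed from the counts of genes with reads of both alleles. Measures per library were compared with exact permutation tests, two-sided, over all splits of the 11 libraries into 5 and 6. Shares of single imprinted genes were compared in the same way over the libraries with allelic reads at the gene. These were all 11 except at COPG2 (5 controls and 5 LOS), KCNQ1 (3 and 4) and TSPAN32 (5 and 2). That test covered genes with a mean of 20 or more allelic reads per library and reads in at least 2 libraries of each group. Intervals of single shares are exact Clopper-Pearson intervals at 95%, which cover counting error only, since reads are not independent molecules.

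Gene lists were tested with camera of limma 3.58.1 on log2 CPM from voom, with a preset correlation of 0.01 between genes. The 32 lists with at least 5 tested genes were adjusted together, and camera with an estimated correlation and fry served as alternatives. The comparisons, tests, gene lists and most alternatives were chosen before the data were examined. The same holds for the rule for named genes. It names up to 12 genes per direction among those past the threshold or, with fewer than 10 such genes, the 10 smallest p in each direction. It adds a fixed set of imprinted genes, up to 4 members of each list with the smallest p, and 6 genes per direction for the sexes and for each allele. Other genes named in the text were chosen after their values were seen. Alternatives were DESeq2 1.42.0, limma voom, other scaling factors, other filters on low counts, no sex term, a replicate block, and each library left out in turn. Fits without the assembled loci, and without the mitochondrial genes, ribosomal RNA and LOC112444681, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

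The tests of LOS against control, of gene lists, of the allelic share and of the maternal allele were tested on simulated data, while those of the sexes, the interaction, each sex alone and the paternal allele were not. In simulated counts for 16587 genes, the test of LOS against control recovered 10% of genes changed 1.5-fold, 62% at 2-fold, 82% at 4-fold and 100% at 8-fold, with 2 false calls. The test of the allelic share, on 5696 simulated genes, recovered 4%, 44%, 92% and 98% at the same folds of the maternal to paternal odds. It gave 9 false calls. That simulation assumed the same spread between libraries at every gene, so recovery at real genes may differ. The test of the maternal allele, on 4242 genes, recovered 26%, 82%, 100% and 100% at the same folds of expression, with 11 false calls. Each of these runs of single genes held 50 changed genes at every fold. So many changes ease the Benjamini-Hochberg threshold. The recovery therefore does not hold for data in which few genes change, where it would be lower. Coordinates are those of the deposited tables on ARS-UCD1.2. KCNQ1OT1, PHLDA2 and DLK1 were not analysed here.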

Results

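The series asks how the transcriptome of fibroblasts from fetuses with large offspring syndrome (LOS), a fetal overgrowth condition of cattle conceived by assisted reproduction, compares with that of control fetuses; its title sets LOS beside Beckwith-Wiedemann syndrome, a human overgrowth disorder of imprinted genes. Skin fibroblasts of 5 control fetuses (2 females, 3 males) and 6 LOS fetuses (3 females, 3 males) were measured, with 1 library per fetus. Total counts ran from 12084724 in LOS 1 to 19297095 in LOS 6. They averaged 16440000 in controls and 14460000 in LOS, a difference within the spread between libraries (exact permutation p = 0.193, two-sided). The libraries correlated with each other at 0.95 to 0.974 within controls, 0.931 to 0.968 within LOS and 0.941 to 0.973 between the groups, across genes, which are not independent replicates. Fetuses of a group differed by more than counting error: the chi-square per degree of freedom between pairs of libraries of a group was 21.1 to 96.7. Maternal allelic reads came to between 1109515 (LOS 1) and 1979345 (control 2) per library, or 50.47% to 50.85% of the allelic reads.

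In LOS fibroblasts the receptor gene IGF2R, whose product clears insulin-like growth factor 2 from the cell surface and which is imprinted with the maternal allele active, stood at 485 ± 133 CPM (SD, n = 6) against 887 ± 99.8 CPM (SD, n = 5) in controls. All 6 LOS libraries lay below all 5 controls. The aldehyde oxidase gene AOX1 averaged 64.2 ± 19.1 CPM in LOS and 123 ± 21.8 CPM in controls, and ABLIM3, an actin-binding LIM protein gene, 6.02 ± 2.80 CPM against 16.3 ± 5.49 CPM. No gene passed the test across all 16946 genes: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes changed, with a smallest adjusted p of 0.932. At an unadjusted p under 0.05 there were 752 genes, where chance alone gives 847. The 2 groups were fully separate in 39 genes, 16 higher and 23 lower in LOS, or 0.23% of the genes tested against 0.433% by chance. limma voom called 0 genes. DESeq2 called 5, namely IGF2R and AOX1 (adjusted p = 0.000539 each), ABLIM3 (adjusted p = 0.0182), LOC112446407 and the assembled locus MSTRG.21533.

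The genes with the smallest p are given as values, each with an adjusted p of 0.932 by edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. On the lower side in LOS, log2 fold changes were -1.01 ± 0.18 (SE) for AOX1, -0.90 ± 0.16 for IGF2R and -1.48 ± 0.31 for ABLIM3. HMGB1, a chromatin protein gene, averaged 56.2 CPM in LOS and 73.6 CPM in controls (-0.40 ± 0.09), with all LOS libraries below all controls. The transcription factor genes TFAP2A (-1.75 ± 0.46) and FOXO1 (-0.65 ± 0.18) were also lower in all 6 LOS libraries than the control median. So were CPT1A, which carries fatty acids into mitochondria (43.8 against 62.2 CPM, -0.52 ± 0.14), and HSD11B1, which makes active glucocorticoid (11.4 against 28.1 CPM, -1.37 ± 0.38, and -0.90 without control 4). HS6ST1, a heparan sulfate sulfotransferase gene (-0.44 ± 0.12), and the phosphate transporter gene SLC20A2 (-0.35 ± 0.10) complete this side. On the higher side, the ubiquitin protease gene USP43 averaged 8.95 CPM in LOS and 4.99 CPM in controls (0.90 ± 0.20). PRORSD1 was the gene of this side with separate groups (5.96 against 4.10 CPM, 0.55 ± 0.14). Agrin (AGRN) averaged 23.0 against 8.92 CPM (1.39 ± 0.39), with 1 control, control 2, at 16.64 CPM. PTHLH, which encodes parathyroid hormone-related protein, averaged 3.28 against 1.58 CPM (1.15 ± 0.32). Log2 fold changes were 0.64 ± 0.18 for NOCT, 0.80 ± 0.23 for the ganglioside synthesis gene ST3GAL5, 0.84 ± 0.24 for NFATC2 and 0.67 ± 0.20 for IER5. BMT2 (0.38 ± 0.11) and YPEL2 (0.35 ± 0.10) were higher than the control median in all 6 LOS libraries.

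IGF2R stood apart among the imprinted genes. Over the 18 tested genes of the list of maternally expressed imprinted genes, 9 were higher and 9 lower in LOS, and 1, IGF2R, passed when adjusted over the list alone (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00248), against 0 over all genes tested. The gene spans 96197493 to 96300019 of chromosome 9, plus strand. Of the 15 tested paternally expressed genes, 9 were higher and 6 lower, and 0 passed adjusted over the list alone. MEST came closest, at 55.2 ± 15.9 CPM (SD, n = 6) in LOS and 34.5 ± 10.5 CPM (SD, n = 5) in controls (edgeR adjusted p = 0.172 over the list alone). The growth factor gene IGF2 and the neighbouring non-coding RNA gene H19 varied widely within both groups. IGF2 ranged from 17.4 to 612 CPM in controls and from 10.1 to 376 CPM in LOS (log2 fold change -0.84 ± 1.18). H19 averaged 907 ± 537 CPM in controls and 531 ± 730 CPM in LOS (-1.52 ± 1.1), with 1985 CPM in LOS 1. CDKN1C, a growth-restraining cell cycle inhibitor gene, averaged 11.7 ± 1.67 and 9.14 ± 6.86 CPM (-0.41 ± 0.35). Log2 fold changes were 0.41 ± 0.22 for MEG3, 0.17 ± 0.17 for GRB10, -0.04 ± 0.10 for GNAS, -0.05 ± 0.21 for PLAGL1, -0.37 ± 0.46 for PEG3 and -0.10 ± 0.31 for PEG10. Leaving out single libraries turned the sign of IGF2 (0.06 without control 3), PEG3 (0.18 without control 4), GNAS (0.02 without control 2), PLAGL1 (0.06 without control 5, 0.07 without LOS 4) and PEG10 (0.25 without control 5, 0.01 without LOS 5). Without changing sign, H19 moved to -0.91 without LOS 6 and to -2.19 without control 2. Likewise CDKN1C moved to -0.80 without LOS 5 and -0.26 without LOS 1, and GRB10 to 0.34 without control 2 and 0.29 without LOS 1. KCNQ1 had 0 to 5 counts and AIRN, the antisense partner of IGF2R, 0 to 3 counts per library, too few to test. SNRPN was measured in the allelic table alone.

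Near IGF2R, the gene PNLDC1 was also lower in LOS. Of 9 tested genes of that region, 4 were higher and 5 lower in LOS. Adjusted over the list alone, IGF2R (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00124) and PNLDC1 (adjusted p = 0.0386) passed, against 0 over all genes tested. PNLDC1, an RNA exonuclease gene, lay at 2.65 ± 0.67 CPM (SD, n = 6) in LOS and 4.17 ± 0.71 CPM (SD, n = 5) in controls. Log2 fold changes were -0.09 ± 0.08 for WTAP, -0.10 ± 0.15 for SOD2, 0.09 ± 0.25 for ACAT2 and 0.00 ± 0.11 for TCP1. Camera gave an adjusted p of 0.192 for the region, and fry an adjusted p of 0.164 for a change one way and of 0.0124 for changes either way. In insulin-like growth factor and insulin signalling, 18 of 27 tested genes were higher and 9 lower, and 1, IGF2R, passed adjusted over the list alone (edgeR adjusted p = 0.00372). IGF1R, the receptor for growth factor signalling, averaged 519 ± 91.4 CPM in LOS and 369 ± 74.5 CPM in controls (0.50 ± 0.16, adjusted p = 0.0713 over the list alone), and FOXO1 had an adjusted p of 0.0582 over the list alone. The list as a whole did not pass (camera adjusted p = 0.801), its median log2 fold being 0.06 and its mean -0.03.

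**Figure D1:**
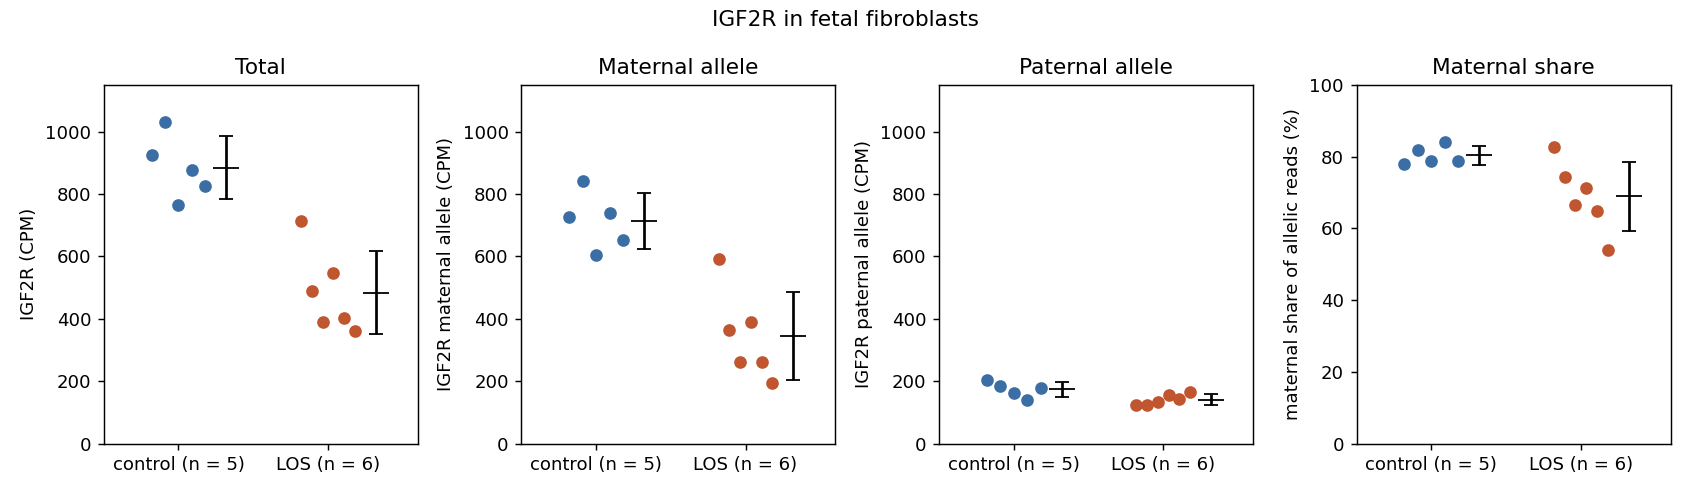
IGF2R in each library, in CPM for the total, the maternal allele and the paternal allele, and as the maternal percentage of allelic reads. Dots are single fetuses, 5 controls and 6 LOS, and bars are the mean and SD; the LOS totals, at 361 to 714 CPM, all lie below the controls, at 767 to 1030 CPM.

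Among the gene lists, cell cycle genes tended to be lower and ribosomal protein genes higher in LOS, by a test that did not hold with an estimated correlation between genes (adjusted p = 0.803 each). Of 38 proliferation genes, 37 were lower in LOS, with a median log2 fold of -0.42. Examples are CDC45 (5.09 against 6.70 CPM, -0.47 ± 0.15), KIF20A (13.4 against 21.7 CPM, -0.72 ± 0.39) and PCNA (-0.46 ± 0.25). LOS 1 stood apart, with CDC45 at 8.12 CPM and PCNA at 22.7 CPM against at most 5.65 and 15.3 CPM in the other LOS libraries. Without control 5 KIF20A had a log2 fold of -0.40. Camera with the preset correlation gave the list an adjusted p of 1.6e-09; the adjusted p = 0.803 with an estimated correlation, which was 0.654 between its genes. Of 36 ribosomal protein genes, 35 were higher, with a median log2 fold of 0.15 and values of 0.36 ± 0.11 for RPS24 and 0.24 ± 0.11 for RPLP0. Their adjusted p was 1.6e-09 by camera with the preset correlation, and the adjusted p = 0.803 with an estimated correlation. All 13 mitochondrially encoded genes were lower (median -0.15; -0.24 ± 0.11 for ND4 and -0.24 ± 0.13 for ND1), with a camera adjusted p of 0.00366, and adjusted p = 0.803 with an estimated correlation. Mitochondrial genes took 2.76% ± 0.30 (SD, n = 5) of counts in controls and 2.44% ± 0.22 (SD, n = 6) in LOS (exact permutation p = 0.0606). Of 17 genes of cell cycle arrest and p53 response, 13 were higher (median 0.25), among them GADD45A (41.8 against 26.6 CPM, 0.63 ± 0.21) and TP53INP1 (0.50 ± 0.23, and 0.75 without control 2). That list had a camera adjusted p of 0.0384, and adjusted p = 0.608 with an estimated correlation. Of 20 endoplasmic reticulum stress genes 18 were higher (median 0.13; 0.27 ± 0.12 for the serine synthesis gene PHGDH), with a camera adjusted p of 0.0282, and adjusted p = 0.809 with an estimated correlation. Of 19 immediate early genes 15 were higher (median 0.20), with EGR1 at 940 against 566 CPM (0.71 ± 0.24) and DUSP1 at 0.54 ± 0.23; the camera adjusted p was 0.0482, and adjusted p = 0.803 with an estimated correlation. No member of these 6 lists passed adjusted over the list alone. None of the 6 calls held with an estimated correlation, and fry, which tests a list without comparing it with other genes, called 0 lists as moving one way. With single libraries left out, the mitochondrial call ended without control 5 (camera adjusted p = 0.163), and the p53, stress and immediate early calls ended in 5, 4 and 6 of 11 fits, reaching 0.21, 0.644 and 0.51. Without a sex term the p53 (camera adjusted p = 0.0524) and stress (0.071) calls ended, with a replicate block the stress call (0.681), and without the rows of mitochondrial genes, ribosomal RNA and LOC112444681 the immediate early call (0.0559).

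**Figure D2:**
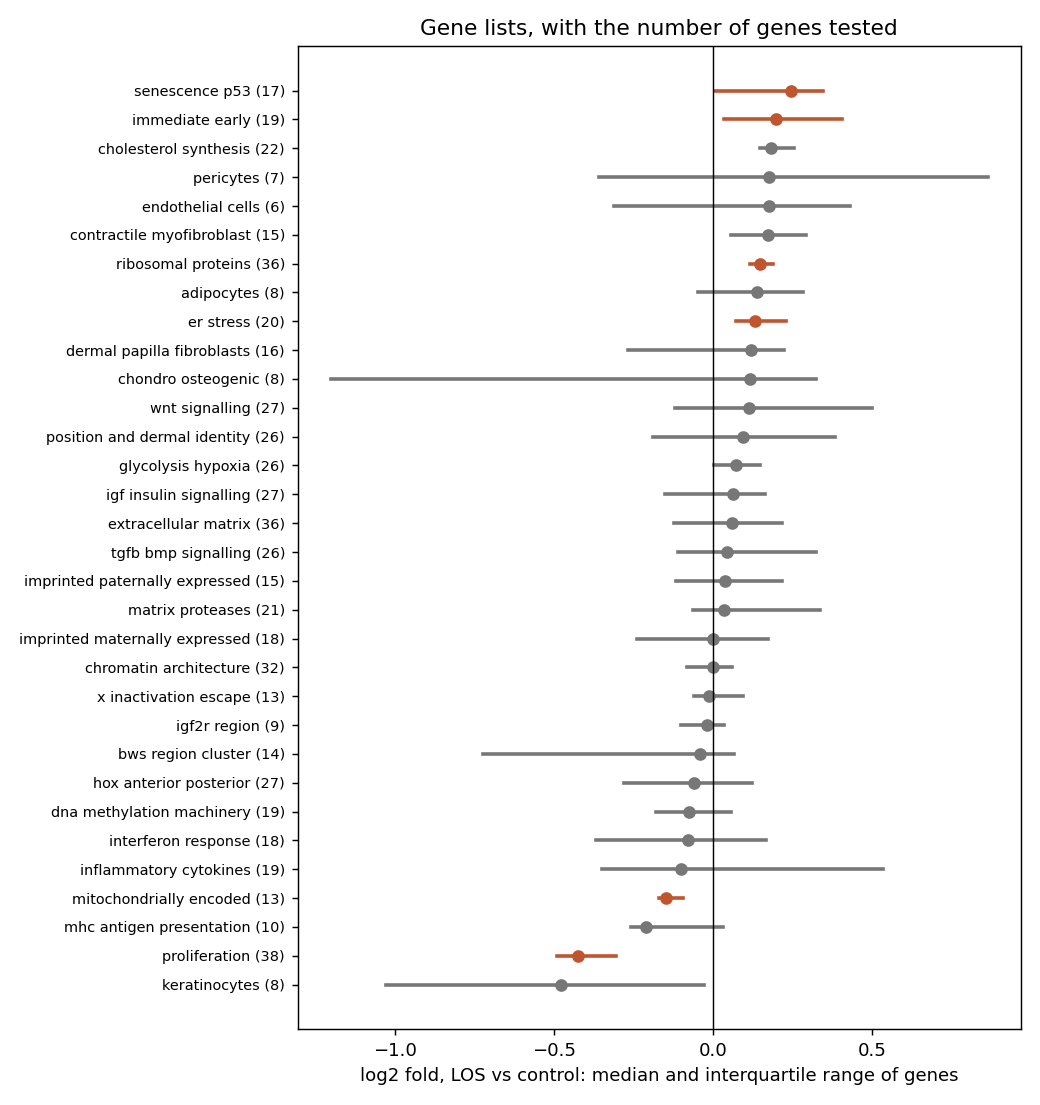
Log2 fold change, LOS against control, of the 32 gene lists with at least 5 tested genes. Dots are the median over the genes of a list and lines the interquartile range; orange marks the 6 lists with a camera adjusted p under 0.05 at the preset correlation, from proliferation at a median of -0.42 to the p53 response at 0.25.

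The other lists did not pass camera. Sterol synthesis genes were higher in 19 of 22 cases (median 0.18, camera adjusted p = 0.0842) and contractile genes in 13 of 15 (median 0.17, adjusted p = 0.0858). With an estimated correlation camera gave each list an adjusted p of 0.809, and the calls that follow used the preset correlation. The sterol list passed without control 2 (adjusted p = 0.00038), control 4 (0.00119), LOS 1 (0.00234), LOS 4 (0.00559) or LOS 5 (0.034). The contractile list passed without control 3 (0.00532), control 5 (0.00743), LOS 3 (0.0213), LOS 5 (0.0276) or LOS 6 (0.0102), glycolysis and hypoxia genes without LOS 5 (0.0484), and the homeobox genes with a replicate block (0.0133). Extracellular matrix genes divided into 20 higher and 16 lower (adjusted p = 0.438), with COL12A1 at 8901 ± 3246 CPM (SD, n = 6) in LOS and 5125 ± 3703 CPM (SD, n = 5) in controls. Matrix proteases and their inhibitors divided into 13 higher and 8 lower (adjusted p = 0.768), and inflammatory cytokines into 9 higher and 10 lower (adjusted p = 0.673), with C3 at 5.22 against 2.54 CPM. In Wnt signalling 16 of 27 were higher (adjusted p = 0.363), with LEF1 at 6.02 against 2.77 CPM. In TGF-beta and BMP signalling 13 of 26 were higher (adjusted p = 0.673), with INHBB at 0.517 against 1.88 CPM and TGFBR1 at 220 against 159 CPM. Glycolysis and hypoxia genes (19 of 26 higher, adjusted p = 0.368), interferon response (7 of 18 higher, 0.768) and antigen presentation (4 of 10 higher, 0.931) did not pass. Nor did the homeobox genes of body position (12 of 27 higher, 0.852) or the factors of limb and dermal identity (17 of 26 higher, 0.446). The DNA methylation machinery had 8 of 19 genes higher (adjusted p = 0.256), with DNMT1 at -0.33 ± 0.20. Cohesin, CTCF and polycomb genes had 16 of 32 higher (adjusted p = 0.823), with CTCF at -0.18 ± 0.09. The lists of maternally and paternally expressed imprinted genes had adjusted p of 0.768 and 0.673, the genes around H19 and KCNQ1 on chromosome 29 an adjusted p of 0.49, and genes that escape X inactivation 0.768. In all these lists 0 genes passed adjusted over the list alone, apart from IGF2R. The median and the mean differ in sign for the paternally expressed imprinted genes, inflammatory cytokines, TGF-beta and BMP signalling, chromatin, escape and cartilage and bone genes, and the camera direction of antigen presentation (up) is opposite to its median of -0.21.

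Markers of other cell types were scarce. Keratinocyte markers were lower in LOS in 8 of 8 tested genes (camera adjusted p = 0.693), from low levels such as 0.327 against 0.574 CPM for KRT5. Endothelial markers (3 of 6 higher, adjusted p = 0.693), pericyte markers (4 of 7, 0.823), adipocyte markers (5 of 8, 0.49) and cartilage and bone markers (4 of 8, 0.898) did not pass. Fibroblast subtype markers did not pass either (10 of 16, 0.673). Lists with fewer than 5 tested genes had no list test. These were muscle (2 genes, CHRNA1 and MYMK), leukocyte (4 genes), melanocyte and Schwann cell (4 genes) and nuclear retained RNA (4 genes), with 0 genes passing adjusted over the list alone. NGFR, a Schwann cell and neural crest marker, averaged 0.862 ± 0.751 CPM (SD, n = 6) in LOS and 5.95 ± 5.87 CPM (SD, n = 5) in controls (edgeR adjusted p = 0.0753 over the list alone). The pseudogene LOC112444681 alone took 1.86% ± 0.43 of counts in controls and 2.47% ± 0.47 in LOS (exact permutation p = 0.0606 over 5 and 6 libraries).

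Single LOS libraries were compared with the controls because weight alone defines the syndrome in the labels. On average 288 ± 125 genes (SD, n = 6) of a LOS library lay more than 2 log2 units from the control median. LOS 6 stood farthest out, with 512 genes. Imprinted genes outside the control range by more than 1 log2 unit numbered 0.667 ± 0.816 (SD, n = 6) per LOS library. The same counts were taken for all splits of the 11 libraries into 6 and 5, a test chosen after the data were seen. The median over the splits was 255 genes and 0.5 imprinted genes, and a share of 0.119 and 0.39 of the splits gave at least the count of LOS against control. With any distance outside the range, LOS libraries had 14.17 imprinted genes on average, the median over splits was 11, and the share was 0.0649.

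Male and female fibroblasts differed in XIST, EIF2S3, TDRD9 and 5 assembled loci. XIST, the RNA of the inactive X, stood at 883 ± 127 CPM (SD, n = 5) in females and 0.539 ± 0.149 CPM (SD, n = 6) in males, and its level matched the sex label in all 11 libraries. EIF2S3, an X-linked translation factor gene that escapes inactivation, fell by 0.65 ± 0.08 on the log2 scale in males, from 229 to 145 CPM. TDRD9 (chromosome 21, 68471596 to 68583010), a germline RNA helicase gene, had 0 CPM in all 5 females and 0.987 ± 0.186 CPM in the 6 males. Across 16946 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 8 changed, 1 higher in males (TDRD9, adjusted p = 0.0191) and 7 lower. The 7 were XIST (adjusted p = 9.1e-11), EIF2S3 (adjusted p = 0.0169) and the assembled loci MSTRG.14990, MSTRG.19755, MSTRG.22266, MSTRG.6670 and MSTRG.7685. Of the 8, 3 lie on the X and 5 on autosomes, and 560 genes had an unadjusted p under 0.05 where chance gives 847. Of 13 tested genes of the list of escape from X inactivation, 11 were lower in males. Adjusted over the list alone 7 passed, against 2 over all genes tested. These were lower in males apart from OFD1, which was higher (log2 fold 0.39, edgeR adjusted p = 0.0182 over the list alone). TXLNG averaged 7.53 CPM in males against 12.6 CPM in females. DDX3X, at 357 against 408 CPM, did not pass (adjusted p = 0.085 over the list alone). Of 11 Y-linked genes listed, 0 were in the table, so DDX3Y, EIF2S3Y and UTY were not analysed here. With no Y-linked gene measured, whether the reads assigned to TDRD9 in males came from its chromosome 21 locus was not tested. Nor was it tested whether male reads of Y-linked copies were assigned to X-linked genes of the escape list, OFD1 included. Without single libraries the count was 3 to 7: EIF2S3 stayed called without control 3, control 4, LOS 1 or LOS 3 (edgeR adjusted p up to 0.0826 otherwise) and TDRD9 without LOS 1, LOS 2 or LOS 3 (up to 0.0948 otherwise). Of the assembled loci, MSTRG.14990 and MSTRG.22266 were called in all 11 fits, as was XIST. MSTRG.6670 was called without control 4, LOS 1, LOS 2 or LOS 3 (up to 0.0948 otherwise), MSTRG.7685 without control 4 or control 5 (up to 0.198 otherwise) and MSTRG.19755 without LOS 1 alone (up to 0.126 otherwise). limma voom did not call MSTRG.19755 (adjusted p = 0.0688) or MSTRG.6670 (adjusted p = 0.0796). Without the assembled loci 3 genes were called, EIF2S3, TDRD9 and XIST.

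The effect of LOS was not shown to differ between the sexes. The test of the group by sex interaction gave 0 of 17583 genes by edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, with 870 genes at an unadjusted p under 0.05 where chance gives 879. limma voom gave 0. DESeq2 called 6 genes: BRINP1, CYP1B1, RN18S1 and the assembled loci MSTRG.22799, MSTRG.9284 and MSTRG.9856. CYP1B1, a cytochrome that oxidises steroids and xenobiotics, had a log2 fold of 1.07 in females and -1.92 in males by edgeR. BRINP1 had -3.19 in females and 1.63 in males. Within females edgeR called 0 genes (705 at an unadjusted p under 0.05, DESeq2 5) and within males 0 genes (1044 at an unadjusted p under 0.05, DESeq2 27). Without LOS 1, edgeR called 2 genes within females, LOC104974678 and MSTRG.12005.

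The balance between parental alleles was close to even at the median gene, while single genes lay to either side. In controls the median gene had 49.83% maternal reads, and means per gene ran from 22.65% to 82.09%. A gene read from 1 allele alone would be missing from this range. Across 5696 autosomal genes, edgeR's quasi-likelihood test of the allelic share with Benjamini-Hochberg adjustment called 0 genes changed between LOS and control. An unadjusted p under 0.05 was found for 246 genes, where chance gives 285. The smallest p belonged to IGF1R (chromosome 21, 7780293 to 8080968), with 47.2% ± 4.46 maternal reads in LOS and 38.3% ± 3.29 in controls (edgeR adjusted p = 0.353). The genes that followed included GHITM, at 45.02% against 56.35% maternal reads, EFCAB14, at 52.99% against 61.90%, and TLDC1, at 48.9% against 37.9% (edgeR adjusted p = 0.640 each). Leaving out 1 library brought 1 gene past the threshold in 3 cases: IGF2R without LOS 1 (edgeR adjusted p = 0.0346), NREP without control 2 (edgeR adjusted p = 0.00511) and SMAGP without LOS 2 (edgeR adjusted p = 0.0381).

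Measured per parental allele, IGF2R was lower on the maternal side. Its maternal allele averaged 344 ± 141 CPM (SD, n = 6) in LOS and 713 ± 90.8 CPM (SD, n = 5) in controls, with every LOS library below every control. Its paternal allele averaged 141 ± 16.9 CPM in LOS and 174 ± 24.8 CPM in controls, with 3 of 6 LOS libraries below all controls. The maternal allele of GADD45A averaged 23.5 ± 3.82 CPM in LOS and 13.4 ± 1.78 CPM in controls, and that of IGF1R 245 ± 48.1 against 143 ± 37.8 CPM. Over 4245 genes the maternal allele gave 0 changed genes (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), with 195 at an unadjusted p under 0.05 where chance gives 212. The smallest adjusted p was 0.42, for GADD45A. Over 4248 genes the paternal allele gave 0, with 187 at an unadjusted p under 0.05 and a smallest edgeR adjusted p of 0.935. IGF2R had a log2 fold of -1.11 ± 0.22 for the maternal allele (edgeR adjusted p = 0.646; exact permutation p = 0.00433) and -0.30 ± 0.13 for the paternal allele (edgeR adjusted p = 0.935; exact permutation p = 0.0346). With the raw allelic counts in place of the split totals, the paternal value was 0.23. Raw allelic counts also depend on the heterozygous sites covered in a library, so that value does not measure expression alone. In controls, IGF2R had from 413 allelic reads for 11769 counts (control 5) to 2289 for 20816 (control 2). In LOS it had from 394 for 7477 (LOS 4) to 848 for 5358 (LOS 5). Other maternal alleles with small p were higher for LIMK2, WFDC1, SLC2A3 and ELL, at 0.47 to 1.52 log2 units, and lower for ZNF326, PAMR1, XYLT1, CPT1A and FOXO1, at -1.22 to -0.53. On the paternal side GHITM, IER5, PLEKHA2, ST3GAL5, SQSTM1 and EFCAB14 had values of 0.36 to 1.15. HSD11B1, RALGPS2, FLYWCH2, NFIB, ECHDC2 and RMDN1 had values of -1.43 to -0.47.

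Of the 14 imprinted genes with a mean of 20 or more allelic reads per library and reads in at least 2 libraries of each group, IGF2R had the highest maternal share. Its maternal share was 80.3% ± 2.62 (SD, n = 5) in controls, from 78.1% to 84.2%, and 69.0% ± 9.68 (SD, n = 6) in LOS. Single LOS fetuses ranged from 82.6% in LOS 1 (95% interval 79.8% to 85.2%, 799 reads) to 54.0% in LOS 6 (50.1% to 57.9%, 648 reads). The difference of -11.4 points had an exact permutation p of 0.0346, and 0.485 after adjustment over the 14 imprinted genes tested, of which 0 passed. With single libraries left out the exact p ran from 0.00794 without LOS 1 to 0.0714 without control 4. The edgeR quasi-likelihood test of the same share (log2 ratio -0.87 ± 0.23) had a Benjamini-Hochberg adjusted p of 0.640 over all genes and 0.0102 adjusted over the list alone, here the 12 imprinted genes that met the limits on reads of this test. UBE3A, NAP1L4, TRAPPC9, INPP5F, GRB10, CD81, TSSC4, OSBPL5, PPP1R9A, TFPI2 and TSPAN32 had between 41.5% and 59.5% maternal reads in both groups. Outside this range lay COPG2, at 35.9% in controls and 37.08% in LOS, and KCNQ1, at 26.77% and 31.28%. The KCNQ1 mean of controls rests on 6, 4 and 22 reads in controls 1, 2 and 4. In its LOS mean the 7 reads of LOS 5 weigh as much as the 1021 of LOS 3. Most reads assigned to KCNQ1 in LOS 1, LOS 2 and LOS 3 may not be its own, as described below. For GRB10 the shares were 51.4% ± 1.82 in controls and 49.6% ± 3.54 in LOS.

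At several other imprinted genes, reads of both alleles appeared in single LOS libraries and hardly at all in controls. SNRPN had 177, 260 and 251 allelic reads in LOS 2, LOS 3 and LOS 5, with maternal shares of 18.1% (95% interval 12.7% to 24.6%), 25.8% (20.6% to 31.5%) and 33.1% (27.3% to 39.3%). It had 7 reads in control 4 and 0 in the other 7 libraries. LOC100848941 had 80, 157 and 154 reads and MAGEL2 24, 26 and 72 reads in LOS 2, LOS 3 and LOS 5, against at most 5 and 0 reads in controls. LOC100848941 is on neither list of imprinted genes and was chosen after its values were seen. KCNQ1 had 981, 189 and 1021 reads in LOS 1, LOS 2 and LOS 3, against at most 22 in a control. Its counts in these LOS libraries were 2, 1 and 1, so most of these reads were not counted as KCNQ1. PEG10 (276 reads) and SGCE (482 reads) had such reads in LOS 2 alone, and MEG8 in LOS 1 (59 reads) and LOS 2 (8 reads). A library without allelic reads at a gene had no heterozygous site, reads of 1 allele alone or too few reads of the gene. The allelic table does not separate these. Total counts argue against too few reads in controls at PEG10, SGCE and MEG8. PEG10 was at 54.0 to 159 CPM in controls and 82.8 CPM in LOS 2, and SGCE at 49.5 to 70.9 and 61.4 CPM. MEG8 was at 99.8 to 119 CPM in controls and 100.5 CPM in LOS 1. MAGEL2, at 6.04 to 12.1 CPM in controls and 15.4 CPM in LOS 5, stays open.

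**Figure D3:**
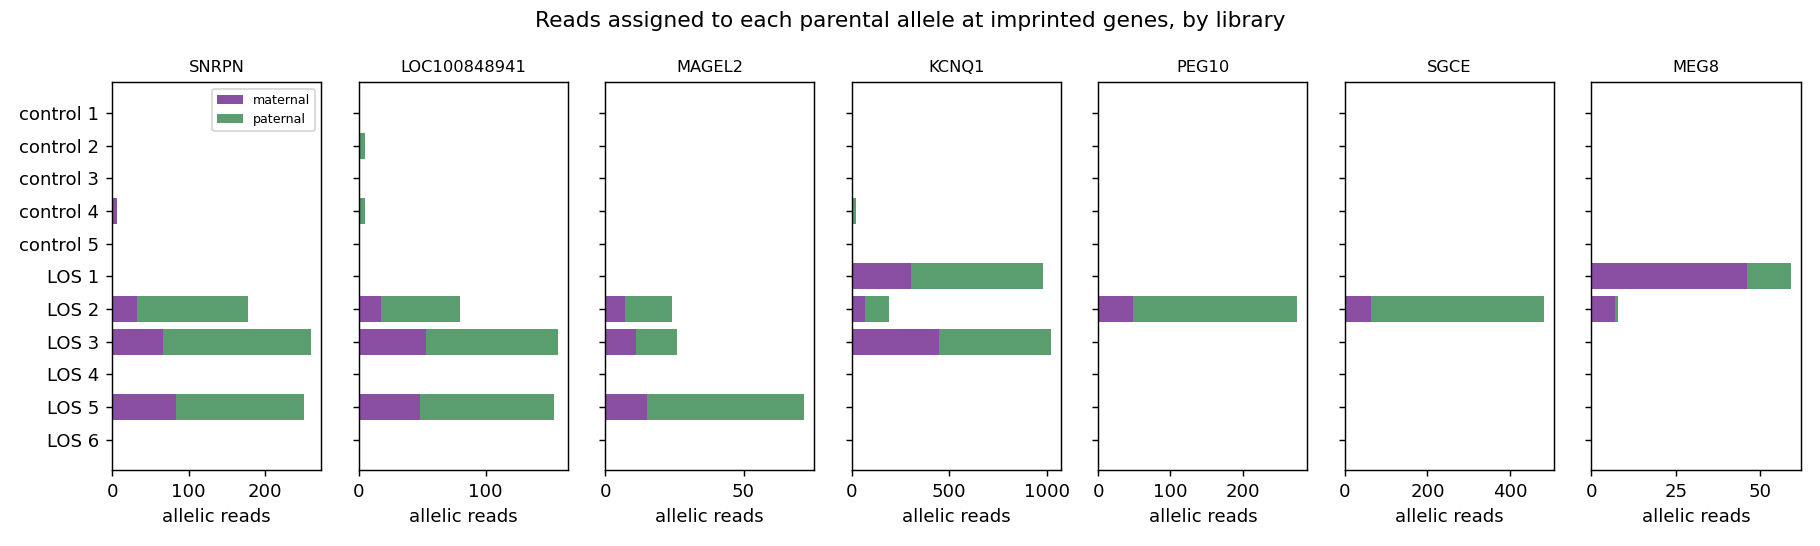
Allelic reads per library at 6 imprinted genes and LOC100848941, which is on neither list of imprinted genes, maternal in purple and paternal in green. The x axis is the number of reads and differs between panels. At SNRPN, LOC100848941 and MAGEL2 reads of both alleles are seen in LOS 2, LOS 3 and LOS 5, and controls have at most 7 reads.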

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

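The tests of why IGF2R was lower and of the reads from both alleles at imprinted genes were chosen after those results were seen, while the counts over other splits of the samples were planned.

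Total IGF2R was lower in LOS, more so on the maternal allele. A difference in scaling between libraries is argued against, since the least negative log2 fold with 3 kinds of library factors was -0.9006. A shift of allelic ratios across all genes is argued against as well: the median change of the maternal share over 5696 genes was -0.1461 points, against -11.4 points at IGF2R, and 2.09% of genes lay as low. A loss from both alleles alike stays open, because the exact permutation p of the maternal share, 0.0346 with all libraries, reached 0.07143 without control 4 and ran from 0.00794 (without LOS 1) upwards over the libraries left out. A partial loss of maternal expression at this imprinted gene in some LOS fetuses is a candidate explanation, a hypothesis found and tested on the same data, with conception method, body weight and culture among the causes not tested.

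Reads from both alleles appeared at imprinted genes in LOS libraries that had hardly any in controls: 260 at SNRPN in LOS 3, 72 at MAGEL2 in LOS 5, 276 at PEG10 and 482 at SGCE in LOS 2, and 59 at MEG8 in LOS 1. With 50 reads as the minimum, 6 of 22 imprinted genes (27.3%) and 4.36% of 9694 other genes had such reads in LOS alone, against 0 imprinted genes and 6.23% of others in controls alone. X-linked genes were not removed from the other genes. Neighbouring genes such as PEG10 and SGCE had them in the same fetuses, so the genes are not independent. Per library the difference was within the spread, with 12 ± 2.1 imprinted genes (SD, n = 6) at 50 or more reads in LOS and 10.8 ± 0.837 (SD, n = 5) in controls (exact permutation p = 0.297); LOS 4 had 9 and LOS 6 had 10. Heterozygous sites that differ between fetuses at any gene cannot be told apart from a relaxed imprint, since over all splits of the 11 libraries the two-sided exact permutation p was 0.0455, 0.0455, 0.0476 and 0.0606 at minimums of 10, 20, 50 and 100 reads. The values argue against more allelic reads in the LOS libraries as the whole source: with every library scaled to the smallest, LOS 1, all 6 genes kept 50 or more reads in LOS alone (59 at the least) while controls had at most 12.45 at any of them, and the mean number of genes at 50 reads fell from 4287 to 3885. Unscaled, 4126 ± 267 genes in LOS and 4480 ± 455 in controls had 50 reads. The difference was within the spread (exact permutation p = 0.154), and LOS had fewer such genes rather than more. Allelic reads per library ran from 2.199 to 3.826 M in LOS and from 2.39 to 3.905 M in controls. Scaling down cannot raise a control, and controls had 0 reads at MEG8, SGCE, MAGEL2 and PEG10. The scaled counts therefore show only that the reads in LOS libraries outlast the scaling. At KCNQ1, 1 of the 6 genes, the allelic reads exceeded the count of the gene by up to 1020 in a library. In LOS 1, LOS 2 and LOS 3 it had 2, 1 and 1 counts against 981, 189 and 1021 allelic reads. These values argue against KCNQ1 itself as the source of most of these reads. They may belong to another transcript inside its span, such as LOC112444897 (chromosome 29, 48905879 to 48921626), which was not tested.

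Where the real split called 0 genes, every split gives at least as many, so the count says nothing about chance. This holds for LOS against control (100 splits, highest other 414), the allelic share (45 splits, highest other 3), the maternal allele (100 splits, highest other 45) and the paternal allele (100 splits, highest other 101). For the gene lists chance cannot be excluded, since 30 of 100 splits gave at least the 6 lists of the real split, and the highest other gave 12. For the sexes a count as large was rare, but chance is not excluded. Of 100 splits, 2 gave at least 8 genes, the real one with 8 and another with 382. Splits with such counts point to a structure of the samples, which overlaps the groups in part. The split with 414 genes set controls 1, 3, 4 and 5 with LOS 1 and 4 against the rest. Control 2 with LOS 2 to 6 against the rest gave the 382 genes, in a fit with the group as a term, and the 45 and 101 of the alleles. On the first principal component LOS 1 lay at -57.27, beyond the controls (-35.16 to 7.403), and LOS 2 to 6 at 10.09 to 59.68. What sets LOS 1 and control 2 apart was not tested. Within males, 10 splits are too few for a share under 0.05; the real split gave 0 genes and the highest other 0.

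Single libraries stood far from the rest of their group in 12 of 104 groups of values tested, where chance gives about 5.2. That number assumes normally distributed and independent values. The genes were partly chosen from these data, and several of the values share LOS 1 or control 2. The excess over 5.2 is therefore not evidence of unusual libraries. In control 2 AGRN was at 16.64 CPM against at most 8.31 CPM in the other controls, GRB10 at 93.42 CPM against at most 68.9 CPM, and LOC112444681 took 2.602% of counts. In control 5 PEG10 was at 160 CPM against at most 75.6 CPM, and mitochondrial genes took 3.281% of counts. RPS24 was lowest in control 4, at 216.3 CPM. In LOS 1 H19 was at 1985 CPM against at most 407 CPM in the other LOS libraries, GRB10 at 47.93 CPM and BLCAP at 65.08 CPM, both the lowest of the group. PEG10 was at 129.9 CPM in LOS 3, and LOS 6 had YPEL2 at 51.86 CPM and the largest total, 19.3 M counts.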

How the results depend on the processing

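Fits without the assembled loci, and without mitochondrial genes, ribosomal RNA and LOC112444681, were chosen after the data were seen; the other alternatives were planned. With DESeq2 the counts of genes were 5 for LOS against control, 22 for the sexes, 6 for the interaction, 5 within females and 27 within males; the cause was not tested. With the other scalings, filters and limma voom the LOS, interaction and within-sex counts stayed at 0. For the sexes the count was 5 with autosomal genes alone, the same 5 autosomal calls as in the main fit, since the X-linked calls were left out. It was 3 without the assembled loci and 3 to 7 with each library left out. XIST, MSTRG.14990 and MSTRG.22266 were called in each of those 11 fits. Of the 6 gene lists, 0 passed camera with an estimated correlation and 0 passed fry as moving one way. Without a sex term the p53 and stress lists were lost (adjusted p = 0.0524 and 0.071), and without mitochondrial genes, ribosomal RNA and LOC112444681 the immediate early list was lost (0.0559). Without single libraries 4 to 7 lists passed; the mitochondrial list was lost without control 5 (adjusted p = 0.163), the p53 list without controls 1, 3 and 4 and LOS 1 and 5 (0.0514 to 0.21), the stress list without controls 2 and 4 and LOS 1 and 6 (0.172 to 0.644), and the immediate early list without controls 1, 2 and 5 and LOS 1, 2 and 5 (0.0698 to 0.51). The sterol list was gained without controls 2 and 4 and LOS 1, 4 and 5 (0.00038 to 0.034), the contractile list without controls 3 and 5 and LOS 3, 5 and 6 (0.00532 to 0.0276) and glycolysis and hypoxia without LOS 5 (0.0484). Imprinted genes outside the control range numbered 14.17 per LOS library when any distance counted, where the median over all splits of the libraries was 11. Signs turned within the range over left-out libraries for IGF2 (log2 fold -1.739 to 0.06189), PLAGL1 (-0.1828 to 0.073), PEG3 (-0.7556 to 0.1793), GNAS (-0.07497 to 0.01874) and PEG10 (-0.2999 to 0.2471). The IGF2R paternal allele turned to 0.2314 with raw allelic counts, which also depend on the heterozygous sites covered in each library. Within females the count was 0 to 2 (2 without LOS 1), and the allelic share gave 0 to 1 (1 without control 2, LOS 1 or LOS 2). Without control 1 or 2 a lone control female remains in the fits by sex and is assumed to vary like the others. IGF2R passed over the maternally expressed list in every alternative run, with adjusted p of 0.000265 to 0.0102 over the libraries left out. The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.166 to 0.257, 2 of 5 pairs lay above 0.1, and 2 of 5 controls correlated best with their own number. With the number as a replicate block, LOS against control gave 0 genes, the sexes 2 (XIST and ENTPD1), PEG10 a log2 fold of 0.02392, the stress list an adjusted p of 0.681 and the homeobox list 0.0133, which then passed; it changed no other call of lists or of LOS against control. Of 9716 genes with allelic reads, the limits on reads and the removal of X-linked and mitochondrial genes left 5696 to test. Simulated 2-fold shifts of the maternal to paternal odds were recovered in 44% of cases, with the same spread assumed at every gene and many genes changed at once.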

Other observations

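The correlations and the comparison of the alleles within controls were chosen after the data were seen, and so were all tests of this part.

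IGF2 and H19, neighbours on chromosome 29 that are expressed from opposite alleles, varied together between the fetuses. Over the 11 libraries their log2 CPM correlated at a Pearson r of 0.871 (permutation p = 0.00011, Benjamini-Hochberg adjusted 0.00033 over 3 relations) and a Spearman rho of 0.791 (permutation p = 0.0055, adjusted 0.0082). Without the 2 libraries farthest from the median of IGF2, LOS 4 and LOS 6, r was 0.774, and within the 6 LOS libraries it was 0.882. IGF2 was lowest in LOS 6 (10.1 CPM), LOS 4 (11.9 CPM) and control 2 (17.4 CPM), where H19 was at 12.5, 90.1 and 166 CPM. The non-coding RNA genes MEG3 and MEG8 of chromosome 21 correlated at an r of 0.83 (permutation p = 0.0021, adjusted 0.0032) and a rho of 0.791 (adjusted p = 0.0082). Without LOS 3 and LOS 5 the r was 0.685, and within LOS it was 0.795. IGF2R and its neighbour PNLDC1 correlated at an r of 0.717 (permutation p = 0.017, adjusted 0.017) and a rho of 0.664 (permutation p = 0.031, adjusted 0.031). That relation was 0.55 without LOS 3 and LOS 6 and 0.121 within the 6 LOS libraries. Both genes were lower in LOS, which by itself makes them correlate over the 11 libraries. The r of 0.717 therefore does not show a relation within a group. The relation was not tested within the controls, so whether any remains there stays open.

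Within the 5 control fetuses the maternal and paternal alleles differed at 523 of 5696 genes (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), 312 higher on the maternal and 211 higher on the paternal allele. Among these hybrids the parent and the breed of an allele are the same thing wherever all crosses ran one way, which was not analysed here. Of all the genes 2 had a mean maternal share above 80% in controls and 0 a share below 20%.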
